A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

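Total RNA of fission yeast (*Schizosaccharomyces pombe*) was hybridized to Affymetrix yeast arrays that also carry probe sets for budding yeast (*Saccharomyces cerevisiae*). The samples were 3 arrays of wild-type cells and 3 arrays of cells lacking isp7, grown exponentially in a minimal medium with ammonium chloride, and RNA was extracted with hot phenol per the labels' protocols. The deposited values are log2 probe set values, 1 per probe set and array. They were made with RMA in Partek version 6.5 per the submitters' processing notes. RMA corrects the background of each array, brings all arrays to 1 distribution of probe values, and summarizes the probes of a probe set on the log2 scale. It compresses differences near the background and near saturation, and it removes any change in total RNA per cell. The table's 10928 probe sets ranged from 4.03 to 15.65. All 6 columns of values were used, and no column was left over.

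Probe sets were named from the platform annotation given for the array, with symbols updated through gene IDs in the RefSeq gene table of assembly ASM294v3. That table was used for names, gene lengths and neighbouring genes, and no coordinates are printed because the sources used here name no build for the array. Names were given for 5538 probe sets, 20 of which have several genes and were not used to name any. A total of 2917 probe sets, for 2899 genes, matched an *S. pombe* gene, 3 of them by symbol because the gene ID had been retired, and 113 symbols differed from the older annotation. For 14 genes more than 1 probe set was present. Another 2601 probe sets carry *S. cerevisiae* names, 213 are control or reporter probe sets and 5177 have no gene name here. Genes without a named probe set were not analysed here, among them SPBPB2B2.01, which the rule for named genes lists.

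The background was set at percentile 95 of the mean values of the *S. cerevisiae* probe sets, 7.08 on the log2 scale, and 97.6% of the *S. pombe* probe sets had a mean above it. An array has no read depth, and the number of arrays limits the precision. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these arrays, which may be partly technical. No scan date or other batch label was given in the sources used here.

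The comparison was isp7 null minus wild type, fitted to the 2917 *S. pombe* probe sets with limma 3.58.1 (lmFit and eBayes with no trend and no robust prior) in R 4.3.3, with p-values that are two-sided and adjusted by Benjamini and Hochberg. The thresholds follow the series' design text, which names a false discovery rate of 0.05 with fold changes of 1.5 and 2. In the report, rose and fell mean an adjusted p under 0.05 and a change of at least 1.5-fold, unless a list test is named. Errors are SD over 3 arrays for values per group and SE of the limma fit for log2 changes.

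Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule names isp7, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, every called member of the amino acid permease list, up to 3 called members of each other list by size, and tor1, tor2, tsc2, gad8, ura4, put4, isp5, per1 and SPBPB2B2.01 whatever their values. To complete counts of 5 or fewer, mfm2, amt2, gdh2, ppp1, glt1, gst2, dak2, ssc1, lys4, arg7, rli1, bms1, frp1, srx1, gal10, ght5 and ams2 were named after their values had been seen. Where a gene has several probe sets, the one with the highest mean is given. For 2 list entries an older name leads to a gene of another function, and both were left out. List tests used limma's camera with a preset inter-gene correlation of 0.01 on values averaged per gene. They were repeated with a correlation estimated per list and with fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. The list of Tf2 retrotransposons had no measured member, which left 25 lists.

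The fitting code was tested on simulated values with the spread of these arrays. Of 50 probe sets changed by 1.2-fold, 86% were recovered. At 1.5-fold, 2-fold and 4-fold 100% of 50 each were recovered. Of 2717 unchanged probe sets 10 were called, 4.93% of all calls, and no call had the wrong direction. The simulated spread was drawn from the distribution that limma had fitted, with independent noise and no array effect, gene correlation or length trend. Far fewer probe sets were changed than the 70.7% past the adjusted p in the data. The simulation therefore checks the code and not the error rates of the real comparison.

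The alternatives were an intensity trend or a robust prior in eBayes, no variance moderation, the replicate number as a block, repeated quantile normalization over *S. pombe* probe sets, median centring, a filter on the background, all probe sets of the array, averaging of probe sets per gene, and leaving out each array. A correction for gene length, a loess curve of the log2 value on log2 gene length removed from each array's deviations, was added after a trend with length had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.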

Results

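Transcript levels were measured on 6 arrays, 3 of wild-type fission yeast and 3 of an isp7 null strain, both in exponential growth in minimal medium with ammonium as nitrogen source. Isp7 belongs to the family of 2-oxoglutarate- and iron-dependent dioxygenases. The series' title places it in amino acid uptake and in signalling by TOR, the kinase that couples growth to nutrients, and the comparison asks which transcripts depend on it. Arrays of the same group correlated at 0.998 to 0.999 over *S. pombe* probe sets and arrays of different groups at 0.973 to 0.978. The first principal component held 92.8% of the variance. The number of arrays limits the precision of every value below.

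The isp7 transcript itself was at 11.70, 11.63 and 11.55 on the log2 scale in the wild-type arrays and at 6.02, 6.38 and 6.17 in the null arrays, the direction the labels give. Its mean of 11.62 ± 0.073 (SD, n = 3) in wild type and 6.19 ± 0.18 (SD, n = 3) in the null gave a log2 change of -5.43 (SE 0.089, limma adjusted p = 8.75e-08). The null value lies below the background of 7.08, so the size of the drop is limited by the background.

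Among named *S. pombe* genes, each taken by its probe set with the highest mean, those that rose most in the null strain were isp5, mfm1, isp4 and urg1. A further probe set of mfm1 had a log2 change of 4.96, above that of isp5 (4.41). The amino acid permease gene isp5 (SPAC1039.09) went from 10.19 ± 0.40 to 14.59 ± 0.059 (SD, n = 3), a 21.2-fold rise. The M-factor pheromone precursor gene mfm1 (SPAPB8E5.05) rose 19.0-fold, the oligopeptide transporter gene isp4 (SPBC29B5.02c) 9.84-fold and the uracil-regulated gene urg1 (SPAC1002.19) 9.62-fold. The next rises were those of say1 (log2 change 2.51), mmf2 (2.36), str3 (2.36), cao1 (2.19), urg2 (2.02) and zym1 (2.02), of which str3 encodes a transporter of the iron regulon, cao1 a copper amine oxidase and zym1 a metallothionein. After isp7, the named gene that fell most was vht1 (SPAC1B3.16c), which encodes the biotin transporter, with a log2 change of -2.35 (SE 0.033). The other large falls were those of nep2 (-1.48), ubp11 (-1.47), sgt1 (-1.33), mug8 (-1.27), liz1 (-1.23), ipk1 (-1.11), sti1 (-1.06) and set9 (-1.04). Among them nep2 encodes a protease of the ubiquitin-like protein NEDD8, ubp11 a ubiquitin hydrolase, ipk1 an inositol phosphate kinase and set9 a histone methyltransferase. These 20 genes were picked for groups that do not overlap and for an adjusted p under 0.05, so neither is a result of its own. Their limma adjusted p lay between 8.75e-08 and 0.00161. The wild-type arrays were most spread for str3 (SD 0.60) and isp4 (SD 0.46).

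In all, 123 probe sets rose and 128 fell by at least 1.5-fold, 8.60% of the 2917 tested, and 35 rose and 14 fell by at least 2-fold. With the adjusted p alone, 856 were higher and 1205 lower in the null, against 1016 and 1038 with each array centred on its median and 1057 and 1020 after correction for gene length. The groups did not overlap for 76.1% of the probe sets, where chance gives 10%. The split of rises and falls depended on the scaling: with median centring 154 rose and 94 fell by 1.5-fold. After correction for gene length, added once the data had been seen, 133 rose and 72 fell by 1.5-fold. At 2-fold 38 rose and 9 fell with median centring, 35 and 9 with repeated quantile normalization, and 35 and 8 after the gene length correction.

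**Figure D1:**
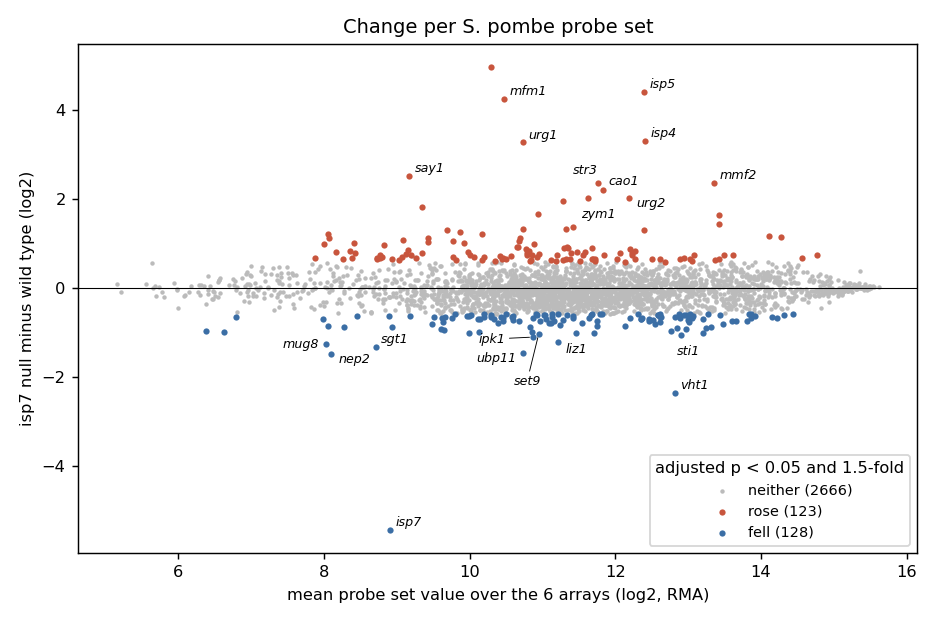
Log2 change, isp7 null minus wild type (vertical axis), against the mean log2 value over the 6 arrays (horizontal axis) for each *S. pombe* probe set, coloured by whether it rose, fell or did neither at adjusted p under 0.05 and 1.5-fold. The 10 largest rises and the 10 largest falls are named; the point above mfm1 is a further probe set of that gene, at 4.96, and isp7 lies lowest at -5.43.

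Amino acid transporter genes changed in both directions. Of 13 measured permeases and transporters, 4 rose and 2 fell, and the counts were the same when adjusted over the list alone. The rises were those of isp5 (log2 change 4.41, SE 0.18), the proline permease gene put4 (1.44, SE 0.049), the plasma membrane permease gene per1 (1.17, SE 0.067) and the vacuolar transporter gene fnx2 (0.61, SE 0.034). The cationic amino acid transporter gene cat1 fell by 1.01 (SE 0.062) and the permease gene aat1 by a log2 change of -0.76 (SE 0.067). All 6 passed limma's adjusted p at 5.90e-05 or less. As a set the list did not pass: its median was -0.04 and its mean 0.42, which differ in sign, with camera adjusted p = 0.464. The list of other nitrogen-source transporters and related carriers, with 9 measured, was also mixed. In it isp4 and the ammonium transporter gene amt1 (1.30, SE 0.057) rose, and vht1, the pantothenate transporter gene liz1 (-1.23) and a further ammonium transporter gene, amt2 (-0.71), fell (camera adjusted p = 0.930).

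**Figure D2:**
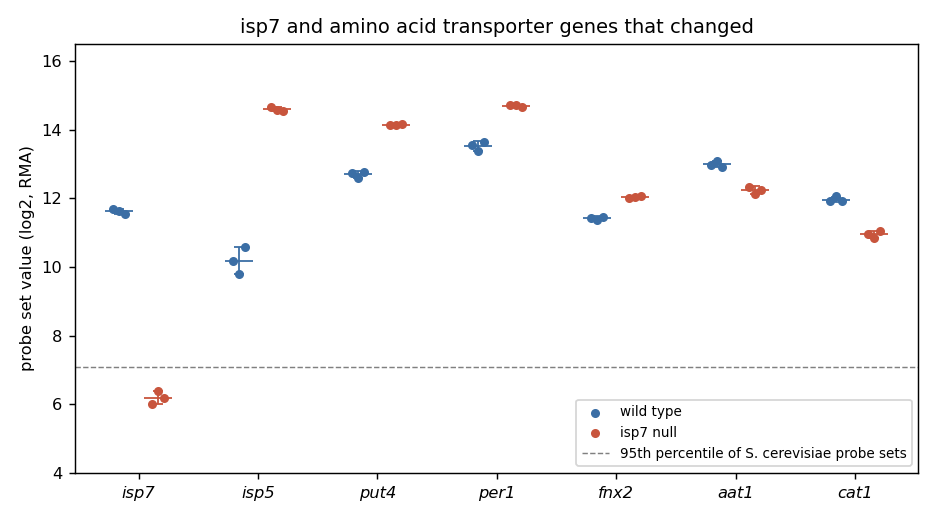
Log2 values (vertical axis) of isp7 and of the 6 amino acid transporter genes that rose or fell (horizontal axis), with 1 point per array, wild type in blue and isp7 null in red, and bars for the mean and SD of 3 arrays. The dashed line is the background of 7.08 from *S. cerevisiae* probe sets; isp7 drops below it in the null arrays, while isp5 goes from 10.19 to 14.59.

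Genes of the nitrogen starvation response were higher in the null strain although the labels give the same ammonium medium for both. Of 26 measured members, 11 rose, among them isp5, isp4, put4, the invertase gene inv1 (1.81, SE 0.39) and mei2 (1.32, SE 0.082), which encodes an RNA-binding regulator of meiosis, and 4 fell, the deleted isp7, gdh2 (-0.81), ppp1 (-0.61) and glt1 (-0.60). The rises isp5 and put4 are also in the permease list and mam2 in the list of M-cell genes. The list's median was 0.32, with camera adjusted p = 0.00949 and adjusted p = 0.311 with an estimated correlation. After the gene length correction the adjusted p was 0.0134.

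Mating genes of the M cell type were higher in the null. Of 8 measured, 4 rose and none fell: mfm1, mfm3 (1.01, SE 0.066), a further pheromone precursor gene, mfm2 (0.75), and mam2 (1.26, SE 0.074), which encodes the receptor for the P-factor pheromone. The list had a median of 0.64 and camera adjusted p = 0.000617, with adjusted p = 0.153 with an estimated correlation and 0.00116 after the gene length correction. The 3 mfm genes encode the same pheromone in near-identical sequences, so their separate values are uncertain; mfm1 has a further probe set with a log2 change of 4.96. Of 5 P-cell genes only map1, the gene of a MADS-box transcription factor, rose (0.76, SE 0.046), and that list did not pass (camera adjusted p = 0.326). In the wider list of sexual differentiation and meiosis 7 of 32 rose and 2 fell. The rises included ste4 (1.37, SE 0.063), which encodes an adaptor of the pheromone response pathway, and mei2, and the falls were those of the cyclin gene cig2 (-0.86) and of spo6 (-0.98), whose wild-type mean of 7.12 lies just above the background and whose null mean of 6.14 lies below it. That list had a median of 0.10 and camera adjusted p = 0.0299, which ended with an estimated correlation (adjusted p = 0.356), with median centring (0.0741), with repeated quantile normalization (0.0607) and after the gene length correction (0.115).

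As sets, genes induced in the core stress response were higher in the null and heat-shock genes were lower. Of 32 measured stress genes 8 rose and 3 fell. The rises included zym1, ish1 (1.33, SE 0.18), a stress-induced gene of the nuclear envelope, and pbi2 (1.15, SE 0.072), which encodes an inhibitor of vacuolar proteinase B. The falls were those of the small heat-shock protein gene hsp16, gst2 (-0.73) and dak2 (-0.88). The median was 0.28 with camera adjusted p = 0.0292, which ended with an estimated correlation (adjusted p = 0.570), with median centring (0.0741), with repeated quantile normalization (0.0768) and after the gene length correction (0.152). Of 15 heat-shock and chaperone genes 4 fell and none rose, led by the co-chaperone genes sti1 (-1.06, SE 0.030) and mas5 (-0.77, SE 0.036) and by hsp16 (-1.02, SE 0.084), with ssc1 at -0.67. Their median was -0.33, with camera adjusted p = 0.00115, adjusted p = 0.153 with an estimated correlation and 0.000570 after the gene length correction, which left 3 falls.

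Several lists of biosynthetic genes were lower in the null. Of 35 measured genes of amino acid biosynthesis outside arginine and lysine, 10 fell and none rose, led by trp1 (-0.97, SE 0.034), leu3 (-0.91, SE 0.033) and his4 (-0.88, SE 0.038). The median was -0.32, with camera adjusted p = 0.000400, adjusted p = 0.171 with an estimated correlation and 0.000114 after the gene length correction, which left 7 falls. In the list of arginine, lysine and urea metabolism 4 of 19 fell, among them the lysine pathway genes lys1 (-1.01, SE 0.033), lys2 (-0.71, SE 0.029) and lys3 (-0.68, SE 0.032) with lys4 at -0.60, and arg7 rose (0.65), and the list did not pass (camera adjusted p = 0.143). Among 14 genes that are in use as auxotrophic markers only lys1 and leu2 (-0.74, SE 0.038) fell. That list was lower as a set, with a median of -0.28, camera adjusted p = 0.000617, adjusted p = 0.284 with an estimated correlation and 3.91e-05 after the gene length correction. It shares his2, his3, his5, his7, leu1 and leu2 with the list of amino acid biosynthesis. With the list of arginine and lysine it shares lys1, arg3 and arg6, so it is not separate from those lists. The marker gene ura4 stood at 13.71 in wild type and 13.45 in the null, a log2 change of -0.25 (SE 0.028, limma adjusted p = 0.000161). Of 38 ribosome biogenesis genes 5 fell and none rose, among them nuc1 (-0.90, SE 0.035), which encodes a subunit of RNA polymerase I, the helicase gene dbp3 (-0.85, SE 0.051) and esf2 (-0.68, SE 0.035), with rli1 at -0.62 and bms1 at -0.61. Their median was -0.34, with camera adjusted p = 0.000167, adjusted p = 0.570 with an estimated correlation and 3.79e-05 after the gene length correction. After that correction 2 of the 38 fell, and esf2 stood at -0.44, short of 1.5-fold. For 119 cytosolic ribosomal protein genes the median was -0.05, none rose or fell, and camera adjusted p was 0.206, with adjusted p = 0.761 with an estimated correlation. With the preset correlation it was 2.87e-15, lower in the null, after the gene length correction, and an estimated correlation was not run on the corrected values. Many of these genes stood near the array's highest value of 15.65, where RMA compresses differences. Their small median change therefore does not show unchanged transcripts. The correction subtracts the rise of other short genes from these compressed values, so the corrected p may partly come from that subtraction.

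Respiratory and histone genes were slightly higher. Of 41 genes of the respiratory chain and ATP synthase, cox17, which encodes a copper chaperone of cytochrome c oxidase, was the only 1 to pass 1.5-fold (0.65, SE 0.035), and the list's median was 0.20. Camera adjusted p was 1.09e-05, with adjusted p = 0.153 with an estimated correlation and 0.000911 after the gene length correction, where cox17 stood at 0.49 and none passed 1.5-fold. None of the 11 genes in the histone list passed 1.5-fold, and 10 of 11 were higher. The lower member was ams2 (-0.33), which encodes a regulator of histone genes. The list had a median of 0.26, camera adjusted p = 0.000664, adjusted p = 0.311 with an estimated correlation and 0.0395 after the gene length correction. Histone genes have near-identical copies, so values of single copies are uncertain.

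**Figure D3:**
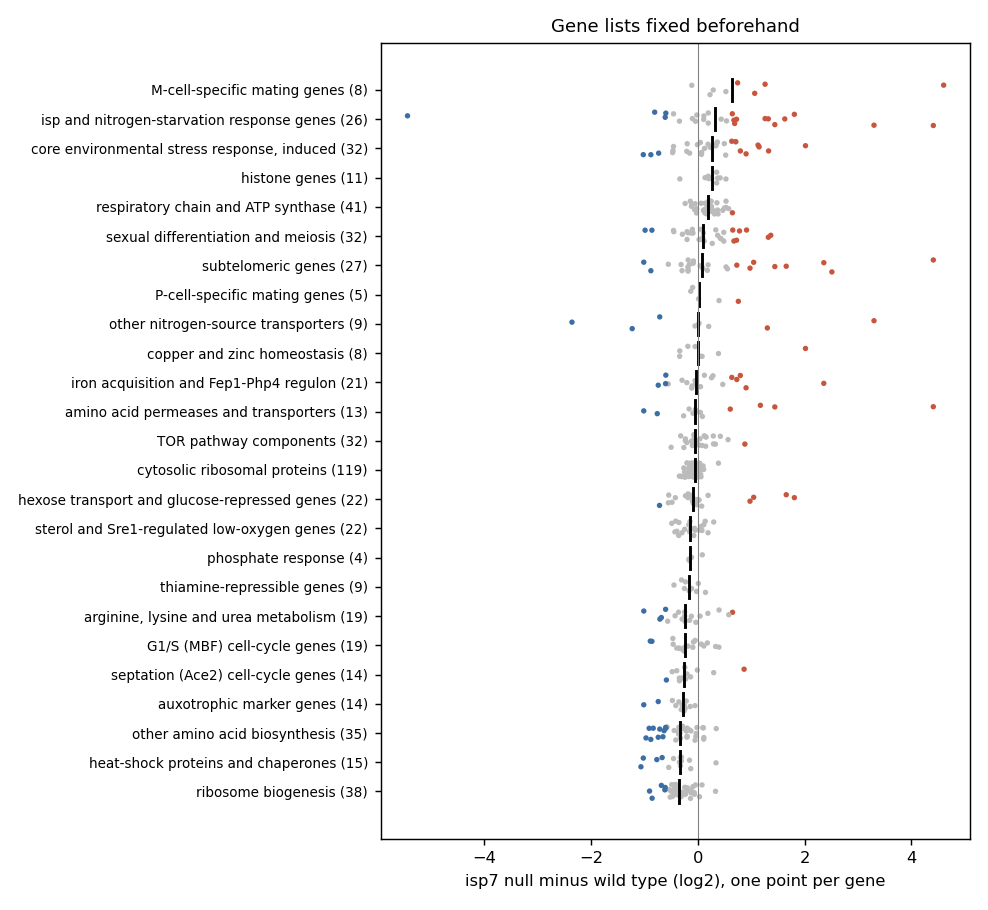
Log2 change, isp7 null minus wild type (horizontal axis), of each measured gene in the 25 lists (vertical axis, number of genes in brackets); red points rose, blue points fell and grey points did neither at adjusted p under 0.05 and 1.5-fold, and black bars are medians. The medians run from 0.64 for the M-cell mating genes to -0.34 for ribosome biogenesis.

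The TOR pathway genes moved little. Of 32 measured components only maf1, which encodes a repressor of RNA polymerase III, rose (0.88, SE 0.078), and the list did not pass (camera adjusted p = 0.558). The log2 changes were 0.002 for tor2 (limma adjusted p = 0.959), -0.10 for tor1 (0.0287), -0.06 for tsc2 (0.110) and 0.12 for gad8 (0.0353), none of them past 1.5-fold. The small values of tor1 and tsc2 change sign after the gene length correction, to 0.15 each, and tor2 goes to 0.26 with limma adjusted p = 0.000241. Leaving out wild-type array 1, wild-type array 3 or null array 1 took the adjusted p of tor1 to between 0.0509 and 0.102, and leaving out wild-type array 2 or 3 or null array 1 or 2 took that of gad8 to between 0.0726 and 0.103. The limma adjusted p of gad8 was 0.0621 with the replicate block and 0.0818 without variance moderation. That of tor1 was 0.169 with median centring and 0.132 with repeated quantile normalization. With all probe sets of the array it was 0.117 for tor1 and 0.107 for gad8.

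In the remaining lists single genes moved without the list. The iron list had 5 rises and 3 falls among 21, with str3, the catalase gene ctt1 (0.91, SE 0.17) and the iron permease gene fip1 (0.80, SE 0.14) higher with frp1 (0.73) and srx1 (0.64). Its falls were leu2, lys4 and glt1, enzyme genes of leucine, lysine and glutamate synthesis (camera adjusted p = 0.559). The hexose and glucose-repressed list had 4 rises and 1 fall among 22, with inv1, the galactose pathway gene gal7 (1.66, SE 0.067) and the maltase gene mal1 (1.05, SE 0.028) higher with gal10 (0.98), and the hexose transporter gene ght5 (-0.71) lower (camera adjusted p = 0.951). Of 27 subtelomeric genes 8 rose and 2 fell, with isp5, say1 and mmf2 among the rises and cat1 and dak2 as the falls (camera adjusted p = 0.0971). The copper and zinc list (1 rise, zym1, among 8, adjusted p = 0.559), the cell cycle lists of G1/S (cig2 and mik1, at -0.89, fell among 19, adjusted p = 0.317) and septation (spo12 rose by 0.87 and adg2 fell by 0.59 among 14, adjusted p = 0.326) did not pass. The same held for phosphate (4 genes, 0.559), thiamine (9 genes, 0.255) and sterol genes (22 genes, 0.416), in which no gene rose or fell. Counts of rises and falls were the same for every list when adjusted over the list alone. Of the 25 lists 10 passed in limma's camera with the preset correlation and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, and 24 passed in fry.

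The change also ran with gene length. Across the *S. pombe* probe sets, which are not independent replicates, Spearman's rho between log2 change and gene length was -0.367 and Pearson's r with log2 length was -0.301. The shortest eighth of genes had a median change of 0.10, with 32 rises and 1 fall, and the longest eighth a median of -0.22, with 4 rises and 31 falls. The slope on log2 length, taken from each array's deviations, was 0.0695 to 0.0792 in the wild-type arrays and -0.0830 to -0.0677 in the null arrays. Among the array's ribosomal RNA controls, the 18S and 28S probe sets had a mean change of -0.46, with 1 of 6 higher, and the short 5.8S RNA had a change of 0.38. The histone list had a median gene length of 829 bases and the respiratory list 1157 bases, against 2018 bases for ribosome biogenesis and 2253 bases for the heat-shock list.

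**Figure D4:**
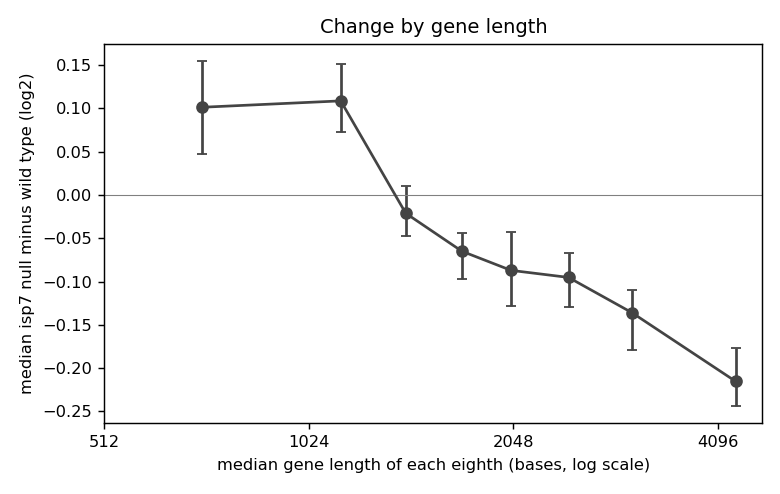
Median log2 change, isp7 null minus wild type (vertical axis), of the *S. pombe* probe sets in eighths of gene length, at the median length of each eighth in bases (horizontal axis, log scale). Bars are 95% bootstrap intervals of the median, which goes from 0.10 in the shortest eighth to -0.22 in the longest.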

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

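A strong signal appeared outside the *S. pombe* genes, in the control and reporter probe sets that the comparisons do not use. A reporter probe set of the array stood at 5.79 ± 0.0103 (SD, n = 3) in wild type, below the background of 7.08, and at 14.33 ± 0.0302 (SD, n = 3) in the null, a log2 change of 8.54 (limma adjusted p = 3.06e-11 over all probe sets) whose size is limited by the background in wild type. The tables used here do not name the engineered sequence it detects, and whether that sequence belongs to the construct that replaced isp7 was not tested. A further reporter probe set named for the same sequence had a log2 change of -0.03. The 5′ control probe set named for the *S. pombe* gene GPD3 had a log2 change of 1.93 (SE 0.13) and its middle control probe set 1.38 (SE 0.059), with all 3 null arrays above all 3 wild-type arrays. The 2 GPD3 control probe sets of the kind that can match further sequences had a mean change of -0.16. A control probe set named for 25S ribosomal RNA was lower in the null, with a log2 change of -1.02 (SE 0.079, limma adjusted p = 7.82e-05 over all probe sets).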

How the results depend on the processing

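The gene length correction was chosen only after the data had been seen; the other alternatives were fixed beforehand. The log2 change of isp7 stayed between -5.53 and -5.27 under every alternative. Leaving out each array in turn gave 1880 to 2047 probe sets past the adjusted p, 242 to 273 at 1.5-fold and 44 to 51 at 2-fold, and 10 lists each time. With all probe sets of the array these counts were 3420, 586 and 170, because more probe sets were tested. Of the 251 calls at 1.5-fold, 217 were shared with median centring, 222 with repeated quantile normalization and 164 with the gene length correction. With the replicate block 252 probe sets passed at 1.5-fold and 1936 with the adjusted p alone. The numbers showed no clear pairing of the samples: deviations of same-numbered arrays correlated at -0.116, -0.251 and 0.108, and only number 3 correlated best with its own number in both groups. Deviations of 3 arrays from their group mean are tied to each other, so a weak pairing is not excluded. No list call changed under the replicate block.

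The list calls changed with the kind of list test and with the correlation it assumes, and the cause of the other changes below was not tested. With an estimated correlation 0 lists passed, with adjusted p = 0.311 for nitrogen starvation and for histones, 0.356 for sexual differentiation, 0.153 for M-cell genes, heat shock and respiration, 0.570 for stress and ribosome biogenesis, 0.284 for markers and 0.171 for amino acid biosynthesis. By fry, which tests lists on their own, 24 passed, with adjusted p = 0.00662 for permeases, 0.00297 for P-cell genes, 0.0101 for copper and zinc, 0.0230 for phosphate, 0.000506 for thiamine, 9.47e-05 for arginine and lysine, 0.00204 for hexose, 0.00487 for sterols, 0.0190 for G1/S, 0.0434 for septation, 0.0106 for ribosomal proteins and 0.000268 for subtelomeric genes. Its direction was opposite to camera's for other nitrogen transporters (4.88e-05) and iron (0.0101). Sexual differentiation and stress ended with quantile normalization (0.0607 and 0.0768), median centring (0.0741 each) and the gene length correction (0.115 and 0.152); over all alternatives their adjusted p ranged from 0.000746 to 0.356 and from 0.00971 to 0.570. Subtelomeric genes passed among probe sets above background (0.0258; range over alternatives 0.000268 to 0.570). With all probe sets thiamine and septation (0.0430 each), arginine and lysine (0.0101), G1/S (0.0333) and ribosomal proteins (0.0130) also passed. Ribosomal proteins passed after the gene length correction (2.87e-15; range to 0.955).

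For 61 named genes and 16 alternatives, 959 of 975 checks kept direction and side of the adjusted p. In 13, all for gad8 or tor1, the adjusted p was lost. After the gene length correction tor1 and tsc2 turned from lower to higher (0.15 each), tor2 passed at 0.26, and esf2 went to -0.44. Genes near the background, among them spo6 and mug8, have compressed changes.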

Other observations

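The tests in this part were chosen after the results had been seen, except the list tests on uncorrected values, the splits of the arrays and the test on ribosomal protein genes. Genes next to each other were not called together more often than in shuffled calls, by a permutation test. Of 1698 pairs of adjacent measured genes, 14 had both members past 1.5-fold, against a mean of 12.4 when calls were shuffled over genes 10000 times (one-sided permutation p = 0.351), and 8 pairs moved the same way (mean 6.14, p = 0.270). The adjacent genes isp5 and mmf2 rose by 4.41 and 2.36, while the adjacent permease genes put4 and cat1 went in opposite directions (1.44 and -1.01). The measured neighbour of isp7, mal2, which was named after its value was seen, had a log2 change of -0.29 (limma adjusted p = 0.00319).

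Probe sets without a gene name held further changes, with 194 higher and 132 lower at 1.5-fold. Among them were 1771089_at (4.73) and 1774284_at (3.91), and 1771750_at (-3.37) and 1778239_at (-2.97). The wild-type mean of 1774284_at, 6.37, lies below the background of 7.08, so its change has no exact size. Of 2601 *S. cerevisiae* probe sets 0 passed limma's adjusted p with 1.5-fold, with or without variance moderation, while 124 passed the adjusted p alone and 303 an unadjusted p under 0.05. Probe sets of 18S and 28S ribosomal RNA had a mean change of -0.46 over 6, with 1 higher, and 5.8S ribosomal RNA had a change of 0.38. The poly(A) spike-ins had a mean change of 0.22 over 12, with 10 higher and 7 past limma's adjusted p. The hybridization spike-ins had a mean of 0.14 over 9, with 9 higher and 6 past it. Spike-ins do not come from the cells, so group differences of this size can arise from preparation or scaling. The medians of the respiratory (0.20) and histone (0.26) lists were of similar size.

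The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2061 probe sets past the adjusted p, 251 at 1.5-fold and 49 at 2-fold, and the highest of the other splits gave 0 in each case by limma, so that 1 of 10 splits reached the real count. At an unadjusted p under 0.05 the real split gave 2127 and the highest other 28, and without variance moderation the highest other gave 0 past the adjusted p. For lists the real split gave 10 and the highest other 11, and 3 of the 10 splits gave as many. Each other split puts 2 arrays of a group and 1 of the other group on each side. The difference between the strains then widens the spread within each side, which holds down the calls of probe sets. The counts of 0 and 28 therefore do not show what chance alone would give.

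As a list, nitrogen starvation genes were higher in the null in an ammonium medium, with 11 of 26 rising and 4 falling (camera adjusted p = 0.00949, and adjusted p = 0.311 with an estimated correlation). A release of silencing near chromosome ends is not enough for all of the rises. Of 24 members outside the subtelomeric list 9 rose, against 3.90% of other genes (Fisher's exact p = 2.2e-07). That test treats genes measured on the same arrays as independent. The median of these 24 was 0.20 (95% interval -0.04 to 0.68), so it does not show a shift of the set. The trend with gene length is not the whole of the list's change at the preset correlation. After the correction 13 members rose, the median was 0.48 and the adjusted p was 0.0134. An estimated correlation ends the list's call before any correction (adjusted p = 0.311). A general stress or late growth phase predicted lower ribosomal protein genes, whose median was -0.053, above the bound of -0.1 set beforehand. After the gene length correction the median was -0.169, below that bound. Neither value decides, because many of these genes stood near the array's highest value of 15.65, where changes are compressed. Short genes also run higher with the length trend, and the correction subtracts that trend from values with little room to rise. General stress or late growth therefore cannot be told apart from a response to the loss of isp7. A preparation batch shared with the strain also stays open.

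As a list, the M-cell mating genes were higher in the null (camera adjusted p = 0.000617, and adjusted p = 0.153 with an estimated correlation). Shared probes of the pheromone genes do not account for the other M-cell genes. Of these, 4 of 5 were higher past the adjusted p, against 29.2% of other genes (Fisher's exact p = 0.0281). That test treats genes measured on the same arrays as independent. Only mam2 (1.26) of the 5 rose by 1.5-fold, and their median was 0.29 (95% interval -0.11 to 1.26). As a set, these 5 genes do not settle whether the pattern holds without the pheromone genes. Strains of opposite mating type would leave M-cell genes at background in wild type. In all 3 wild-type arrays 8 of 8 lay above it. That count alone does not settle the mating types, because 97.6% of all *S. pombe* probe sets had a mean above that background. The measured P-cell genes also lay above it in every array of both groups. Opposite types would also leave P-cell genes lower in the null. Past limma's adjusted p, 2 of the 5 were higher there and 0 lower. Wild-type means of the M-cell genes ran from 8.08 for mfm1 to 14.40 for mfm2. For the measured genes these values argue against a P-type wild type and an M-type null. After the gene length correction 5 of 8 rose and the list's adjusted p was 0.00116 at the preset correlation; without correction an estimated correlation ends the call (adjusted p = 0.153). The hypothesis that loss of isp7 raises M-cell transcripts in ammonium medium came from these same values and has no separate test here. Other differences in mating type between the strains and a preparation batch shared with the strain stay open.

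Shorter genes were higher and longer genes lower in the null. Differences between single arrays do not give it: the gap between groups in slope was 0.137, against a range of at most 0.0153 within a group. The called genes and lists do not carry it, since rho was -0.382 (95% interval -0.416 to -0.345) without them. RNA broken or copied less far from the 3′ end stays open, because the controls disagree. The 5′ against the 3′ probe sets of 6 control genes had a mean change of 0.00898 (95% interval -0.108 to 0.126). Between the longest and shortest eighths of genes it was -0.317, so these 6 genes show no such loss. The change of the long ribosomal RNAs minus that of the short 5.8S RNA was -0.84. That contrast rests on 1 probe set for 5.8S, compares different RNAs and does not measure distance from a 3′ end. Within 18S the 3′ probe set (-0.93), not the 5′ one (0.19), was lower. Within 28S the 3′ probe set (-0.58) and the middle one (-0.76) were lower than the 5′ one (-0.28). A preparation batch shared with the strain and a biological change tied to gene length stay open too.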
